A study of Rattus norvegicus and Homo sapiens with 17 samples.

How the data were processed

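The series held 17 RNA sequencing libraries of total RNA from 2 organisms. Human trophoblast stem cells, which can form the cell types of the placental epithelium, had received a control shRNA or an shRNA against ASCL2 and were differentiated for 8 days toward extravillous trophoblast (EVT), the trophoblast that invades the uterus. Each of these groups had 4 libraries. Rat placental discs of gestation day 12.5 came from 5 wild type and 4 Ascl2 mutant samples. The labels did not say whether replicates were separate cultures, litters or animals, so no p-value below measures more than the spread between these samples. The tests of overlap between organisms measure none of that spread, as they count genes as independent units.

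Per the labels' protocols, cDNA libraries were made with TruSeq RNA kits and sequenced as paired reads of 100 bp on a HiSeq 2000. Reads were mapped in CLC Genomics Workbench 12.0 to the rat genome of Ensembl Rnor 5.0, release 78, and abundance was expressed as RPKM, which scales reads to exon length and to the mapped reads of the library, per the labels' protocols. The protocol of the human samples named the same rat genome, while the submitters' processing notes listed GRCh 37 besides Rnor 5.0. The authors deposited a table for each organism with an RPKM value per transcript and library, for 194432 human and 33349 rat transcripts. Per the file headers, the human table also held a fold change of knockdown over control, and the rat table a fold change of mutant over wild type with the authors' group means. The authors' p-values and false discovery rates came from the EDGE test with tagwise dispersions, per the file headers. The deposited human fold equalled the ratio of the column means (median log2 difference 0.00), whereas the deposited rat fold lay 0.33 above the ratio of the column means on the log2 scale. The deposited rat group means differed by more than 1% from the means of the columns in 62.6% of wild type and 66.0% of mutant transcripts. The authors' columns of means, folds and p-values were therefore used only for a comparison of calls.

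Transcript RPKM was summed per gene symbol, which gave 57772 human and 26079 rat symbols, and the symbol is the identifier the files give. For human samples, 413 symbols of XIST, TSIX and genes on the Y chromosome were left out. A gene was tested when it lay above 0 in any sample, which left 31233 human and 19534 rat genes. Of these, 11760 and 11383 had a mean of at least 1 RPKM, the set used for principal components. No coordinates are given, because the builds in the processing notes differ from those of the reference annotation at hand.

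The files gave no read counts, so depth was estimated from the smallest steps between low RPKM values of genes with a single transcript. The estimates ran from 23.8 to 48.1 M reads (SI prefix mega) in the human libraries and from 12.7 to 15.1 M reads in the rat libraries. At a tolerance of 0.02 of a step, 58.1% to 82.1% of low human values but only 16.0% to 19.9% of low rat values were whole steps, so the rat depths are rough. In control replicates 2 and 4, a further 24.1% and 23.7% of values stood midway between whole steps, against at most 0.3% in the other human libraries. The spread between replicates of a group was 2.92 to 19.0 times the sampling noise of these depths in human and 1.45 to 5.90 times in rat, and no libraries were identical.

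Before the data were examined, the tests, the gene lists, the rule for named genes and most alternatives were fixed. The plan used count models where a table gave counts and limma-trend on log2 of RPKM plus a pseudocount of 1 otherwise, and the latter applied. Each organism had its own fit with group as the only term. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes tested in the organism, with a threshold of 0.05. Log2 fold changes are on the scale of RPKM plus 1 and understate the change of genes with low values. Values below are group means with SD, and fold changes carry the SE of the limma fit.

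A set of 15 human and 17 rat gene lists was tested with limma camera at an inter-gene correlation of 0.01, adjusted over the lists of the organism. Of 276 human and 269 rat list members, 2 and 14 were not listed in the tables. Camera was repeated with the correlation estimated per list, and with fry, whose p-value tests whether a list's genes move one way on balance. Its mixed p-value (PValue.Mixed) tests for change in either direction. Neither compares the list with other genes. The named genes were ASCL2, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 RPKM in a group and no overlap between the groups' libraries, and up to 4 members of each list with the smallest p-values. Across organisms, the 10 genes called in both were named that ranked first by the larger of their p-values. Genes were matched between organisms by symbol, ignoring case. Overlaps were tested with two-sided Fisher's exact tests, and differences in response with an interaction term in a joint limma fit.

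Whether equal replicate numbers pair samples was checked from the correlation across genes of deviations from the group means. In rat, the same-number correlations were 0.408, 0.182, 0.311 and 0.285, each the highest of its sample, so the numbers paired the samples and a fit with the pair as a block was run. The labels do not say what a pair shares, and wild type replicate 5 had no partner. In human, the same-number correlations were -0.608, 0.081, -0.278 and -0.111, so the check gave no sign that the numbers paired the samples. It could not exclude shared cultures, because the deviations of most human libraries also carried trends on GC content. The Spearman rho with GC content was -0.83 in control replicate 4 and 0.72 in knockdown replicate 2, and the deviations of these 2 libraries correlated at -0.714.

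The fits were tested on simulated data in which 50 genes were changed at each fold. With 31227 human genes simulated, 24% of genes changed 1.5-fold, 40% of those changed 2-fold, 80% of those changed 4-fold and 94% of those changed 8-fold were recovered, and 7.0% of calls were unchanged genes. With 19533 rat genes the shares were 46%, 76%, 98% and 100%, with 6.4% of calls unchanged. Far fewer genes were changed than were called in the real data. The adjustment is stricter when few genes change, so the recovered shares may understate recovery in the real data. In both simulations camera and fry called the raised list and 0 of 20 unchanged lists. The simulated genes varied independently of each other. These runs therefore cannot show how often the list tests call unchanged lists whose genes vary together.

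Alternatives were a pseudocount of 0.1, filters on low RPKM, scaling between libraries by median ratio, upper quartile or equal sum, tests per transcript, the replicate block, the rat erythroid genes left out, each library left out in turn, control replicates 2 and 4 left out together, and removal of trends on GC content within human groups. That removal leaves the fold changes as they are and lowers only the spread between replicates, so a GC difference between the groups stays in and more genes can pass. GC content was available for 10602 (90.2%) of the human genes with a mean of at least 1 RPKM. Calculations used R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8), and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. All per-sample columns were used, and 9 gene names in an unheaded last column of the human table were not used here.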

Results

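Gene expression was measured by RNA sequencing in human EVT cells after 8 days of differentiation, with control shRNA (n = 4) or ASCL2 shRNA (n = 4), and in rat placental discs of gestation day 12.5, wild type (n = 5) or Ascl2 mutant (n = 4). Estimated depth in M reads (SI prefix mega) was 43.5, 42.1, 32.7 and 48.1 in control replicates 1 to 4 and 41.9, 23.8, 37.4 and 43.4 in knockdown replicates 1 to 4. In rat it was roughly 12.9, 13.4, 13.7, 14.5 and 13.8 in the wild types and 15.1, 12.7, 14.8 and 14.9 in the mutants. The question posed by the series is how ASCL2, a basic helix-loop-helix transcription factor, acts on trophoblast lineages in both organisms.

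ASCL2 was lower in every knockdown library than in every control library. Its RPKM was 22.5, 21.0, 24.9 and 18.3 in control replicates 1 to 4 and 4.76, 4.87, 4.80 and 4.97 in knockdown replicates 1 to 4. The mean fell from 21.6 ± 2.76 RPKM (SD, n = 4) to 4.85 ± 0.0949 RPKM (SD, n = 4), a log2 fold change of -1.94 ± 0.10 (SE; limma adjusted p = 2.98e-05). In rat, Ascl2 RPKM was 35.8, 70.1, 62.8, 43.7 and 72.3 in wild type replicates 1 to 5 and 0.254, 0.855, 1.5 and 0.596 in mutant replicates 1 to 4. The mean fell from 56.9 ± 16.3 RPKM (SD, n = 5) to 0.802 ± 0.528 RPKM (SD, n = 4), a log2 fold change of -5.00 ± 0.25 (SE; limma adjusted p = 2.06e-05). The titles of the mutant libraries say Het, the genotype label says Ascl2 mutant and the series design says null. The labels do not state which part of the gene is altered, so the rat value checks the labels only if the counted exons lie in that part.

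**Figure D1:**
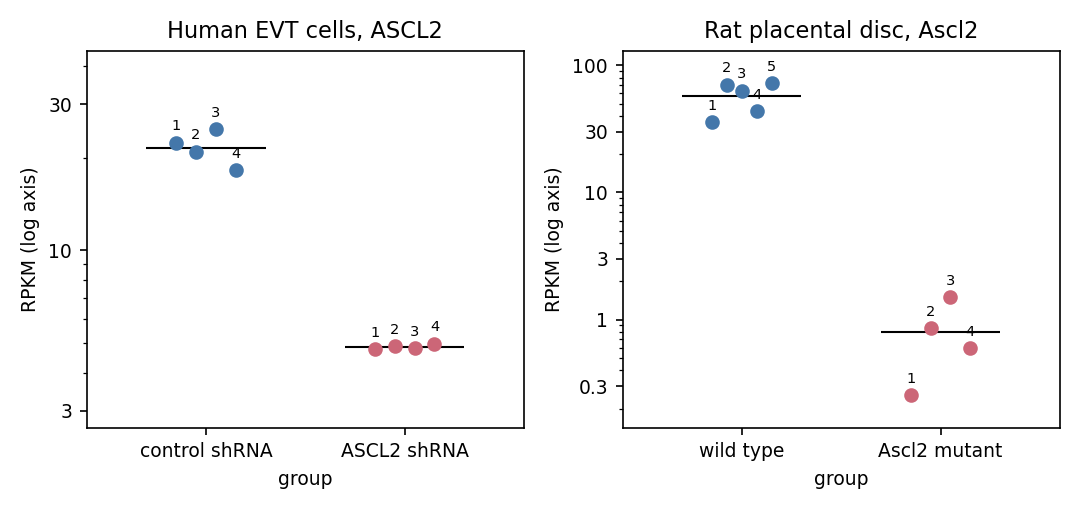
ASCL2 in each human library and Ascl2 in each rat library. The vertical axis is RPKM on a log axis, each point is a library with its replicate number, and the line is the group mean. The human means are 21.6 and 4.85 RPKM and the rat means 56.9 and 0.802 RPKM, with no overlap between groups.

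With ASCL2 knocked down, human EVT cells had higher transcript levels of syncytiotrophoblast genes, which mark the multinucleate, hormone-secreting layer of the placenta, and lower levels of EVT genes. Both lists passed the camera test, each with an adjusted p = 0.298 with an estimated correlation. The placental galectin LGALS14 rose from 2.61 ± 1.14 to 119 ± 18.7 RPKM (SD, n = 4 each), and PSG5, a pregnancy-specific glycoprotein, from 306 ± 65.0 to 1971 ± 63.7 RPKM. HPGD, which inactivates prostaglandins, fell from 171 ± 20.9 to 38.3 ± 8.98 RPKM, and PLAC8 from 120 ± 7.01 to 37.2 ± 4.49 RPKM. The imprinted growth factor gene IGF2 fell from 316 ± 70.8 to 59.7 ± 9.53 RPKM. These genes had limma adjusted p-values of at most 0.000155.

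By limma, 5159 of 31233 genes changed, 2866 up and 2293 down, and 1223 of them changed at least 2-fold, 764 up and 459 down. Control replicates 2 and 4, in which many low values stood between whole-read steps, lay farthest from the knockdown libraries on the first principal component (70.2% of variance), at -41.1 and -62.9 against -19.0 and -15.7 for controls 1 and 3. Without these 2 libraries 3728 genes changed, 1857 up and 1871 down, and 946 changed at least 2-fold. The median log2 fold change of genes with a mean of at least 1 RPKM was 0.05, and -0.08 with upper-quartile scaling, under which falls (2454) outnumbered rises (2243).

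The largest rises besides LGALS14 (log2 fold change 5.11 ± 0.24, SE) were in the vessel regulator ANGPT2 (3.95 ± 0.16), the placental peptide hormone gene KISS1 (3.94 ± 0.73), the chorionic gonadotropin genes CGB, CGB5 and CGB8 (3.47, 3.47 and 3.37), the serine protease inhibitor TFPI2 (3.46 ± 0.23), the inhibin subunit INHA (3.44 ± 0.50), SEMA3B (3.39 ± 0.32) and the transglutaminase TGM2 (3.37 ± 0.46). CGB, CGB5 and CGB8 have near-identical sequences, so their reads are hard to assign. Their adjusted p-values were 0.0484, 0.0388 and 0.0341. Leaving out control replicate 2 or any of the knockdown libraries ended these calls, with adjusted p from 0.0513 for CGB8 to 0.117 for CGB. Without control replicate 4 the log2 fold changes of CGB, CGB5 and CGB8 were 2.48, 2.55 and 2.49, and without control replicates 2 and 4 they were 1.92 (adjusted p = 0.0757), 2.00 (0.0654) and 1.95 (0.0371). Without these 2 libraries the folds of KISS1 (2.66), INHA (2.63), TGM2 (2.51), ANKRD19P (-1.88) and HLA-J (-1.73) were also smaller by over 1.5 times. TFPI2 reached 1007 ± 26.7 RPKM from 95.1 ± 31.4 RPKM (SD, n = 4). The largest falls were in PIPOX, which degrades pipecolic acid and sarcosine (-3.53 ± 0.07), from 65.6 ± 5.01 to 4.76 ± 0.168 RPKM, and in OLFML1 (-3.04), MAMDC2 (-2.81), the phospholipase PLA2G7 (-2.76), the intermediate filament gene NES (-2.73), PDE6H (-2.51), the pseudogene ANKRD19P (-2.51), HLA-J (-2.43), IGF2 (-2.36) and the myosin light chain MYL4 (-2.34). These ranks hold among called genes whose groups' libraries did not overlap, so the absence of overlap was set by the naming rule.

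Of 33 syncytiotrophoblast genes, 29 rose, 2 fell and 2 did not pass the test, with a median log2 fold change of 2.02 (camera adjusted p = 3.55e-17, adjusted p = 0.298 with an estimated correlation). The count adjusted over the list alone was 29 up and 3 down. The list holds several members each of the CGB, PSG, CSH and LGALS families, so its genes are not independent units. PSG4 (2.70 ± 0.15), PSG1 (2.26 ± 0.13) and PSG5 (2.71 ± 0.16) rose, as did CYP19A1, the aromatase that makes estrogens (2.27). GCM1, a transcription factor of syncytial differentiation, fell (-0.79), and so did CSH2, a placental lactogen gene (-1.04). CYP19A1, GCM1 and CSH2 were chosen after their values were seen. Without control replicates 2 and 4, 26 rose and 3 fell.

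Of 30 EVT genes, 16 fell, 2 rose and 12 did not pass the test, with a median log2 fold change of -1.11 (camera adjusted p = 2.37e-09, adjusted p = 0.298 with an estimated correlation). Adjusted over the list alone, 20 fell and 3 rose. PLAC8 (-1.67 ± 0.10), the protease inhibitor SERPINE2 (-1.67 ± 0.12), HPGD (-2.15 ± 0.17) and the deiodinase DIO2 (-1.47 ± 0.12) fell. Also chosen after their values were seen, the nonclassical histocompatibility gene HLA-G fell (-1.60), and LAIR2 (1.48) and PAPPA2 (0.70) rose. Without control replicates 2 and 4, 21 fell and 1 rose. Across 10602 genes, which are not independent replicates, the log2 fold change had a Spearman rho of 0.36 with GC content, and 0.10 without control replicates 2 and 4. With that trend subtracted, the median was 1.96, from 2.02, for the 33 syncytiotrophoblast genes and -1.34, from -1.25, for the 27 EVT genes with a mean of at least 1 RPKM and a GC value.

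Among 14 genes of unfolded protein and amino acid stress, 6 rose and 1 fell, with a median of 0.39 (camera adjusted p = 0.00144, adjusted p = 0.298 with an estimated correlation). When adjusted over the list alone, 9 rose and 1 fell. With GC trends removed within groups 11 rose, while 3 rose when control replicate 1 or 2 or knockdown replicate 3 or 4 was left out. The stress transcription factors ATF3 (1.45 ± 0.13) and DDIT3 (1.34 ± 0.15) and the pseudokinase TRIB3 (0.77 ± 0.14) rose, and the lipoprotein receptor VLDLR fell (-1.23 ± 0.13). Of 22 interferon response genes, 3 fell, STAT2 (-0.99), the RNA sensor DDX58 (-1.45) and BST2 (-1.01), and RSAD2 rose (1.02), with a median of -0.65 (camera adjusted p = 0.00979, adjusted p = 0.618 with an estimated correlation). In the test adjusted over the list alone, 5 fell and 1 rose, as with GC trends removed within groups and without knockdown replicate 2. The interferon list lost its call without knockdown replicate 1 (adjusted p = 0.0610) or knockdown replicate 3 (0.0707), and among genes with a mean of at least 1 RPKM (0.0802) or with at least 1 RPKM in 4 samples (0.0613). Of 31 cell cycle genes, the cyclin genes CCNE1 (-1.73 ± 0.07) and CCNB1 (-1.14 ± 0.28) fell and 29 genes did not pass the test, also when adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.0237, adjusted p = 0.618 with an estimated correlation). CCNB1 lost its call without control replicate 1, 2 or 3 or knockdown replicate 1 or 2 (adjusted p from 0.0521 to 0.0590). The cell cycle list lost its call without control replicate 1 (adjusted p = 0.185), control replicate 3 (0.121), knockdown replicate 1 (0.261) or knockdown replicate 2 (0.157). It also lost it among genes with a mean of at least 1 RPKM (0.0831) or with at least 1 RPKM in 4 samples (0.0795), and with GC trends removed within groups (0.05145), and 4 of its genes fell in each of these settings. Of 8 proximal column genes, the growth factor receptor EGFR (1.55 ± 0.10) and the integrin ITGB6 (0.46 ± 0.13) rose, and 2 rose when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.0493, adjusted p = 0.298 with an estimated correlation). Its call was lost in most settings, with an adjusted p of 0.0509 to 0.0860 when control replicate 2, 3 or 4 or knockdown replicate 1, 3 or 4 was left out, and ITGB6 lost its own when any library but knockdown replicate 2 was left out (0.0678 to 0.132). NOTCH1 (0.15) and TAGLN (0.55) did not pass the test, though they did with GC trends removed within groups (adjusted p = 0.0137 and 0.00455), where 4 genes of the list rose. Without control replicates 2 and 4, 1 proximal column gene rose, 1 cell cycle gene fell, and 2 interferon genes fell and 1 rose, with DDX58 no longer called (adjusted p = 0.0915).

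The other 9 human lists did not pass the camera test. Of 18 stem and villous cytotrophoblast genes, 6 rose, including LRP2 (0.68), and 2 fell, among them the cadherin CDH1 (-1.07), which gave a camera adjusted p of 0.395 and counts of 7 and 3 adjusted over the list alone. Only 4 of these rose without control replicate 4 and 1 without control replicates 2 and 4, with 2 falls in both settings, and LRP2 lost its call with upper-quartile scaling (adjusted p = 0.0564). Of 19 matrix protease and inhibitor genes, 8 fell, including ADAMTS1 (-0.98), and 3 rose, including the elastase MMP12 (1.22). Their median was 0.01 while the mean (-0.07) and the test (Down, 0.444) pointed the other way, and 5 rose and 8 fell adjusted over the list alone, or 7 and 8 with GC trends removed within groups. Without control replicate 2 or knockdown replicate 3 or 4 the counts were 2 and 5. Of 15 epithelial adhesion genes 3 rose and 2 fell, CDH1 and the desmosome gene DSP (-0.65), with an adjusted p of 0.444 and counts of 4 and 3 adjusted over the list alone, or 7 and 3 with GC trends removed within groups. Of 12 fibroblast genes, the matrix gene POSTN (2.60 ± 0.08), TWIST1 (0.96) and COL1A1 (1.08) rose and PDGFRA fell (-0.72), the same counts as adjusted over the list alone, with an adjusted p of 0.277. Of 11 p53 targets, the stress cytokine GDF15 (3.03 ± 0.45) and the cell cycle inhibitor CDKN1A (1.40 ± 0.30) rose, and 3 rose and 1 fell adjusted over the list alone or without control replicate 3. With GC trends removed within groups 4 rose and 3 fell. Without control replicates 2 and 4 the fold of GDF15 was 2.27. The p53 median was -0.02 while the mean (0.48) and the test (Up, 0.535) had the opposite sign. Of 12 Wnt targets, the Wnt deacylase NOTUM (-2.20 ± 0.45) and AXIN2 (-0.44 ± 0.10) fell, also adjusted over the list alone (adjusted p = 0.444). AXIN2 lost its call without control replicate 2 (adjusted p = 0.0536), knockdown replicate 1 (0.0596) or knockdown replicate 2 (0.0527). Of 18 hypoxia and glycolysis genes, 4 rose, including HK2 (0.86), and 6 fell, including P4HA1 (-0.96), with counts of 4 and 7 adjusted over the list alone. Leaving out control replicate 1, 2 or 3 or knockdown replicate 1 or 3 left 2 to 3 rises and 2 to 5 falls. That list's median was -0.15, its mean 0.02 and its test Down (0.392). Of 12 genes near ASCL2 in its imprinted domain, IGF2 and the noncoding H19 fell, also adjusted over the list alone, with an adjusted p of 0.444, a median of 0.02 and a mean of -0.24. With GC trends removed within groups 2 of these genes also rose, and 1 did without knockdown replicate 2. H19 fell from 11180 ± 1913 to 3010 ± 289 RPKM (SD, n = 4 each). Of 15 imprinted genes elsewhere, IGF2R (-0.71), NDN (-0.82) and MEG3 (-0.10) fell and GNAS rose (0.81), the same counts as adjusted over the list alone (adjusted p = 0.328). MEG3 was near 0 in both groups, with means of 0.080 RPKM in the controls and 0.0085 RPKM in the knockdowns. Without control replicates 2 and 4, 0 rose and 1 fell, and MEG3 was no longer called (adjusted p = 0.0907).

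**Figure D2:**
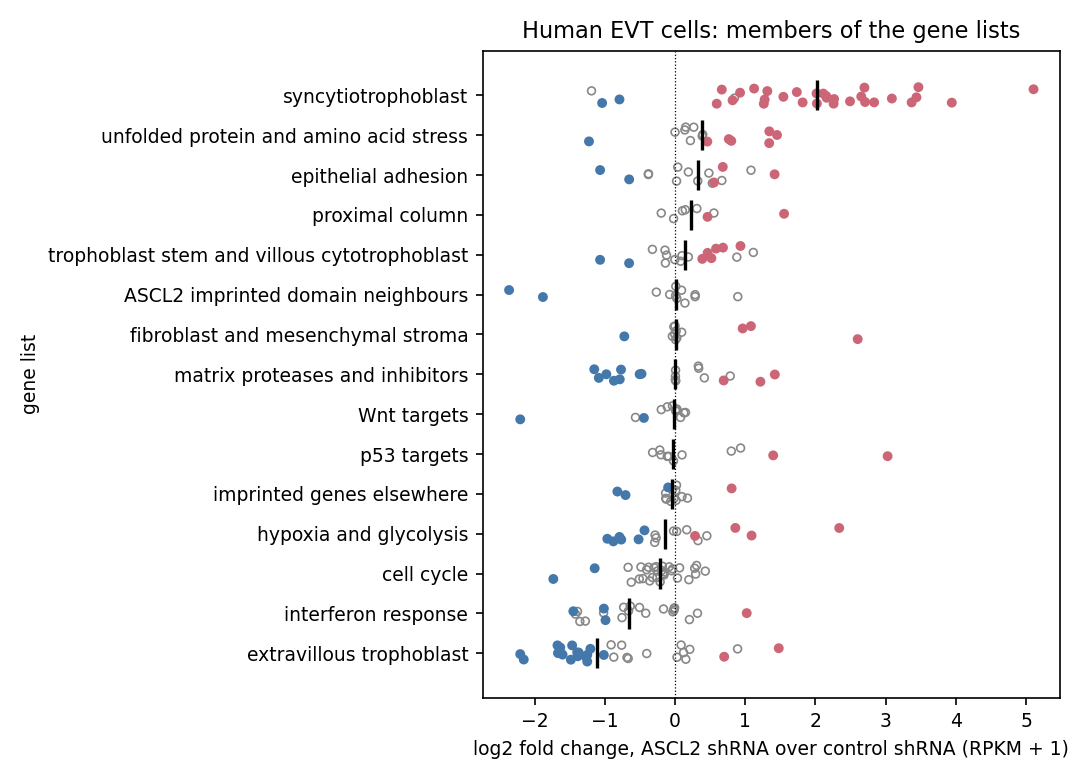
Log2 fold change of each tested member of the human gene lists, ASCL2 shRNA over control shRNA on the scale of RPKM plus 1. Filled points passed the test (red up, blue down), open points did not, and the black line is the list median, 2.02 for syncytiotrophoblast and -1.11 for extravillous trophoblast genes.

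In rat placental discs with mutant Ascl2, genes of the labyrinth, the exchange layer of the placenta, were lower, together with red blood cell and cell cycle genes. These lists passed the camera test, each with an adjusted p = 0.367 with an estimated correlation. Cdx2, a transcription factor of the trophoblast stem cell, fell from 34.5 ± 6.32 (SD, n = 5) to 5.64 ± 1.61 RPKM (SD, n = 4), and the embryonic globin gene Hbz from 6576 ± 2811 to 426 ± 309 RPKM. Prl7b1, a prolactin family gene of invasive trophoblast, fell from 56.2 ± 19.5 to 0.985 ± 0.694 RPKM. Cyp11a1, which starts steroid synthesis and marks giant cells, rose from 151 ± 64.7 to 585 ± 54.3 RPKM, and the heme oxygenase Hmox1 from 183 ± 108 to 723 ± 143 RPKM. These genes had limma adjusted p-values of at most 0.000554.

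By limma, 8356 of 19534 genes changed, 1501 up and 6855 down, and 1547 of them changed at least 2-fold, 247 up and 1300 down. The median log2 fold change of genes with a mean of at least 1 RPKM was -0.27, and with median-ratio scaling between libraries it was -0.02, with 3165 genes up and 4239 down. Medians with that scaling stand beside those of the lists that passed the test. Wild type replicate 1 lay between the groups, at -8.64 on the first principal component (75.6% of variance) against -42.0 to -40.1 for the other wild types and 30.5 to 55.5 for the mutants. Without it 8825 genes changed, 1680 up and 7145 down, and 1822 changed at least 2-fold. With all libraries and replicate pairs as a block, 7758 genes changed, 1379 up and 6379 down, and 1501 changed at least 2-fold.

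The largest rises were in Ceacam15 (log2 fold change 3.16 ± 0.75, SE), in the giant cell hormone gene Prl3d1, listed as Prl3d1_2 (2.53 ± 0.46) and Prl3d1_1 (2.48 ± 0.48), and in Rasd1 (2.22), Hmox1 (2.10 ± 0.31), the chemokine Ccl27 (2.07), Chrdl2 (2.03), Cyp11a1 (2.03 ± 0.24), its electron donor Fdx1 (2.02 ± 0.38) and Fads6 (1.98). This ranking holds among called genes whose groups' libraries did not overlap. Hspa1a_2 (2.65) and Hspa1b (2.51), called but outside that rule, rose more than most of these. The largest falls after Ascl2 itself were in Prl7b1 (-4.85 ± 0.28), the membrane metalloproteinase Mmp15 (-4.74 ± 0.31), the phospholipase Pla2g4d (-4.57), the globin genes Hbe1 (-4.42), Hbz (-4.24 ± 0.57) and Hbg1 (-4.05), Fgfbp1 (-4.23), the adhesion gene Ncam1 (-4.10 ± 0.29) and Doxl1 (-3.87). Ncam1 went from 36.9 ± 10.8 (SD, n = 5) to 1.23 ± 0.799 RPKM (SD, n = 4). Without mutant replicate 4 the falls of Hbe1 (-3.79), Hbz (-3.62) and Hbg1 (-3.44) were smaller by over 1.5 times, and without wild type replicate 1 the rise of Ceacam15 (3.81) was larger by as much. The absence of overlap between the groups' libraries for the ranked genes was set by the naming rule.

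**Figure D3:**
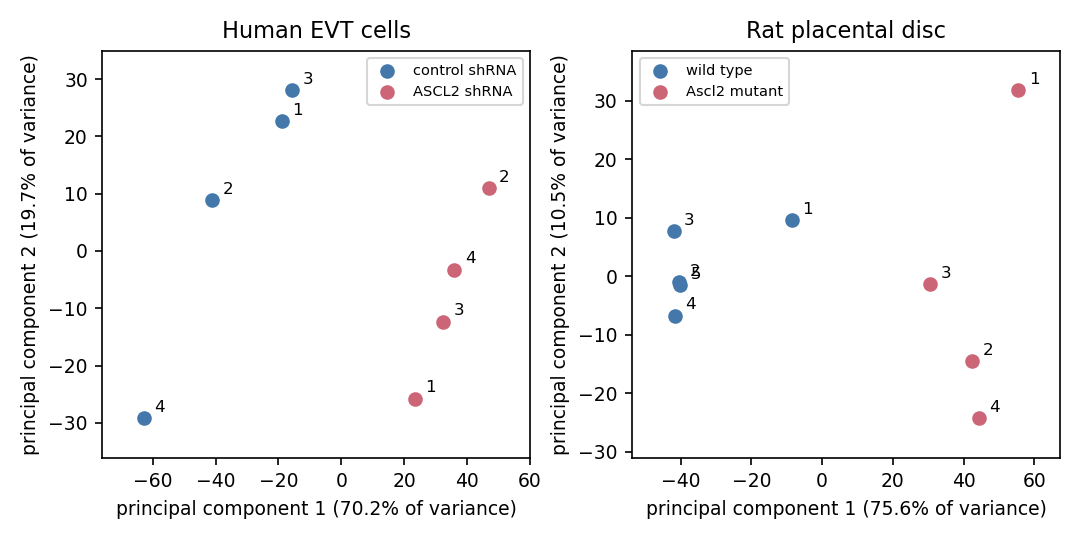
Principal components 1 and 2 of log2(RPKM plus 1) in the human and rat libraries, in arbitrary units, with the percent of variance on each axis. Each point is a library with its replicate number. Wild type replicate 1 sits at -8.64 on the first rat component, between the other wild types and the mutants, and control replicate 4 at -62.9 on the first human component.

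Of 20 labyrinth genes, 18 fell, 0 rose and 2 did not pass the test, with a median of -1.48 (camera adjusted p = 3.16e-05, adjusted p = 0.367 with an estimated correlation). Adjusted over the list alone, 19 fell, and with median-ratio scaling 15 fell and the median was -1.23. The transcription factor Tfeb (-1.62 ± 0.17), the adhesion gene Epcam (-1.89 ± 0.22), the lactate transporter Slc16a3 (-0.86 ± 0.08) and Ly6e (-0.54 ± 0.06) fell. Gcm1 (-2.43) and the fusion gene Syna (-2.09), chosen after their values were seen, fell as well. Of 12 stem and progenitor genes, 7 fell and 0 rose, among them Cdx2 (-2.43 ± 0.18), Elf5 (-2.72 ± 0.27) and the inhibitors of helix-loop-helix factors Id2 (-2.84 ± 0.23) and Id1 (-2.48 ± 0.29). That list had a median of -0.82 (camera adjusted p = 0.0345, adjusted p = 0.367 with an estimated correlation), with 8 down adjusted over the list alone. With median-ratio scaling 6 fell and 1 rose, the median was -0.63 and the list's call was lost (adjusted p = 0.0804), as it was among genes with a mean of at least 1 RPKM (0.0910). Of 30 cell cycle genes, 29 fell, with a median of -1.49 (camera adjusted p = 7.52e-13, adjusted p = 0.367 with an estimated correlation), 30 adjusted over the list alone, and 27 with a median of -1.23 under median-ratio scaling. The mitotic genes Cdc20 (-2.28 ± 0.16), Ccnb1 (-1.64 ± 0.12) and Aurka (-1.71 ± 0.13) and the cyclin Ccne1 (-2.33 ± 0.17) fell.

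Of 18 erythroid genes, 15 fell and 0 rose, with a median of -2.41 (camera adjusted p = 3.16e-05, adjusted p = 0.367 with an estimated correlation). The anion exchanger Slc4a1 (-3.75 ± 0.24), Hemgn (-2.92 ± 0.23), the ammonium transporter Rhag (-2.45 ± 0.21) and the transcription factor Klf1 (-2.86 ± 0.25) fell. Adjusted over the list alone, 15 fell and 1 rose, and with median-ratio scaling the median was -2.27. Of 13 endothelial genes, 10 fell, including Plvap (-2.98 ± 0.31) and the angiopoietin receptor Tek (-1.54 ± 0.16), and 2 rose, with 11 and 2 adjusted over the list alone. Their median was -1.15 and the list did not pass (camera adjusted p = 0.105), but it did with median-ratio scaling (adjusted p = 0.0258). Of 11 mesenchymal genes, 8 fell, including Twist1 (-0.94) and Thy1 (-0.74), and 1 rose, with a median of -1.08 (camera adjusted p = 0.381) and counts of 8 and 2 adjusted over the list alone. Of 14 yolk sac genes, 6 fell, including Gata4 (-1.07) and Sox17 (-1.16), and 0 rose, with a camera adjusted p of 0.262, which became 0.0492 without wild type replicate 1. Of these, 7 fell adjusted over the list alone, 11 fell without wild type replicate 1, 3 fell without wild type replicate 2, 3, 4 or 5 or mutant replicate 1 or 3, and 3 fell and 1 rose with median-ratio scaling.

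Of 12 giant cell entries (11 genes, as Prl3d1 has 2), 7 rose and 3 fell, also adjusted over the list alone, with a median of 0.81 (camera adjusted p = 0.00754, adjusted p = 0.367 with an estimated correlation). Cyp11a1 and both Prl3d1 entries rose, and the prolactin family genes Prl2a1 (-2.11 ± 0.22), Prl2c1 (-2.14 ± 0.23) and Prl4a1 (-2.36 ± 0.30) fell. With median-ratio scaling the counts were 7 and 3, the median was 1.10 and the list's call was lost (adjusted p = 0.0940). With Prl3d1 entered once, 6 rose and 3 fell (adjusted p = 0.0256). Of 10 invasive and glycogen trophoblast genes, 4 fell, including Prl7b1 and Mmp15, and 2 rose, Cited2 (1.78) and Plac8 (1.32), the same counts as adjusted over the list alone (camera adjusted p = 0.872). With median-ratio scaling 4 fell and 3 rose. Of 14 spongiotrophoblast genes, Prl7a3 rose (1.40 ± 0.23), from 3509 ± 1137 (SD, n = 5) to 8948 ± 501 RPKM (SD, n = 4), and Prl5a2 fell (-1.20 ± 0.14), also adjusted over the list alone. The median of that list was -0.20, its mean -0.15 and its test Up (0.238), and with median-ratio scaling 2 rose, 1 fell and the median was 0.02.

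Of 18 hypoxia and glycolysis genes, 10 rose and 2 fell, with a median of 0.43 (camera adjusted p = 0.000113, adjusted p = 0.367 with an estimated correlation). With p-values adjusted over the list alone, 11 rose and 3 fell, and with median-ratio scaling the median was 0.71. The prolyl hydroxylase subunit P4ha1 (0.98 ± 0.15), the hexokinase Hk2 (0.77 ± 0.13) and Bnip3 (0.79 ± 0.14) rose, and the glycolytic regulator Pfkfb3 fell (-1.48 ± 0.20). Of 12 macrophage and leukocyte genes, Csf1r (0.85 ± 0.24), C1qa (0.93 ± 0.27) and Cd68 (1.62 ± 0.53) rose and Lyz2 (1.20) did not pass the test, though it did without wild type replicate 1 (adjusted p = 0.00356). C1qa was low, with means of 0.198 RPKM in the wild types and 1.46 RPKM in the mutants. The list had a median of 0.30 (camera adjusted p = 0.00149, adjusted p = 0.367 with an estimated correlation). Adjusted over the list alone, 2 rose, and with median-ratio scaling 4 rose and the median was 0.40. With replicate pairs as a block, C1qa (adjusted p = 0.0596) and Cd68 (0.0606) no longer passed, and Cd68 also lost its call when wild type replicate 2, 3 or 5 or mutant replicate 2 or 4 was left out, with adjusted p from 0.0613 to 0.0963. None of 8 natural killer cell genes passed the limma test, alone or over all genes (camera adjusted p = 0.242), including Nkg7 (-0.63, unadjusted p = 0.0375) and Gzmm (0.50, unadjusted p = 0.0412). Gzmm passed without wild type replicate 1 (adjusted p = 0.00217) and with median-ratio scaling (0.0220). Of 12 decidual genes, 3 fell, including the phosphatase Alpl (-0.86), and Wnt4 rose (1.06), also adjusted over the list alone. Their median was -0.13 and the test Up (0.369), and with median-ratio scaling 2 rose, 1 fell and the median was 0.13.

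Of 12 genes near Ascl2 in its imprinted domain, 9 fell and 0 rose, also adjusted over the list alone, with a median of -0.47 (camera adjusted p = 0.00794, adjusted p = 0.367 with an estimated correlation). The growth restrainer Phlda2 (-2.46 ± 0.34), the tetraspanin Cd81 (-1.34 ± 0.12), Th (-1.09 ± 0.09) and Nap1l4 (-0.39 ± 0.05) fell. Th was low, with means of 1.20 RPKM in the wild types and 0.0303 RPKM in the mutants. With median-ratio scaling 7 fell and 1 rose, the median was -0.41, and Nap1l4 (-0.10) no longer passed. Among genes with a mean of at least 1 RPKM the list lost its call (adjusted p = 0.181). Of 15 entries (14 genes, as Gnas has 2) of imprinted genes elsewhere, 9 fell, including Ndn (-1.97 ± 0.17) and Mest (-2.22 ± 0.21), and 3 rose, also adjusted over the list alone, with a median of -0.55 (camera adjusted p = 0.330). With median-ratio scaling 6 of them fell and 4 rose. Of 21 interferon response genes, 5 fell, including Stat2 (-1.09 ± 0.13) and Rsad2 (-1.45 ± 0.26), and 1 rose, with 4 and 0 adjusted over the list alone, and 10 and 0 without mutant replicate 4. The median was -0.29, the mean -0.22 and the test Up (0.587).

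**Figure D4:**
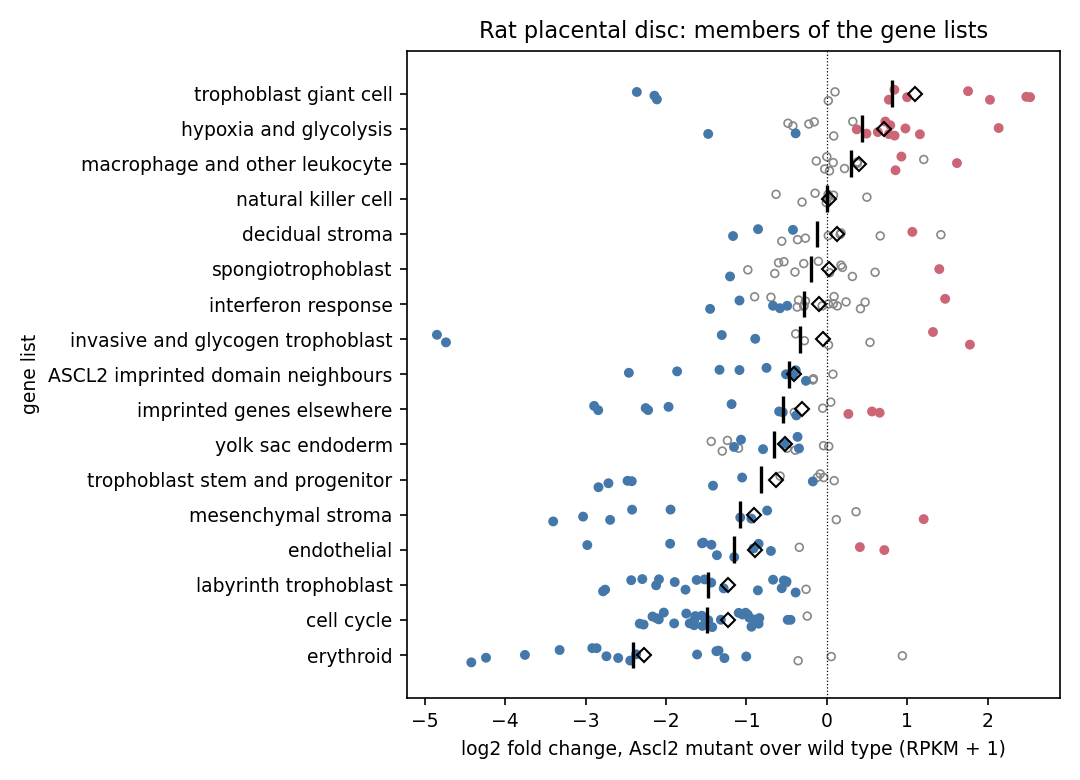
Log2 fold change of each tested member of the rat gene lists, Ascl2 mutant over wild type on the scale of RPKM plus 1. Filled points passed the test (red up, blue down), open points did not, the black line is the list median and the diamond the median with median-ratio scaling. The labyrinth medians are -1.48 and -1.23, and the diamonds of the decidual and spongiotrophoblast lists lie above 0 while their lines lie below.

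The comparison of both organisms asks which genes respond to loss of ASCL2 in the human cells and in the rat discs. The cyclin gene CCNE1 fell in both, by a log2 fold change of -1.73 ± 0.07 in human (SE, n = 4 and 4) and -2.33 ± 0.17 in rat (n = 5 and 4), as did SKP2 (-1.44 and -1.64), which marks cell cycle inhibitors for degradation. The DNA demethylase TET3 (-1.49 and -1.95), LRRFIP1 (-1.57 and -1.21), the RNA-binding RBPMS (-1.20 and -2.09) and the kinase STK24 (-0.89 and -0.58) also fell in both. The phosphatase DUSP4 (1.79 and -1.94), the mitochondrial carrier SLC25A30 (1.39 and -0.83) and TBC1D2B (1.04 and -1.28) rose in human and fell in rat. The interaction term differed from 0 for all of these (limma adjusted p at most 0.0187) except TET3 (0.0688), SKP2 (0.414) and LRRFIP1 (0.106). That term was fitted without scaling between libraries. The general rat shift (median log2 fold change -0.27, against -0.02 with median-ratio scaling) therefore enters each difference. Small differences such as that of CCNE1 may depend on it.

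Over 13819 genes with a shared symbol, 256 rose in both, against 173.9 expected (odds ratio 1.69, Fisher's exact test, p = 2.38e-11, adjusted over the 4 combinations 9.52e-11), and 733 fell in both, against 713 expected (odds ratio 1.06, exact p = 0.292, adjusted 0.292). Rises in human met falls in rat for 804 genes, against 831 expected (exact p = 0.190, adjusted 0.253), and falls in human met rises in rat for 193, against 149.2 expected (exact p = 0.000118, adjusted 0.000236). Among genes changed at least 2-fold in both, 24 rose in both against 8.2 expected (exact p = 2.32e-06) and 57 fell in both against 28.6 expected (exact p = 4.78e-07). The opposite directions were in excess there too, with 66 genes up in human and down in rat against 44.8 expected (exact p = 0.0014) and 12 down in human and up in rat against 5.2 expected (exact p = 0.00639), so this overlap was not limited to shared directions. On the 8326 genes with a mean of at least 1 RPKM in both, 606 fell in both against 658 expected (exact p = 0.00156) and 622 rose in human and fell in rat against 691.5 expected (exact p = 3.85e-05), so these combinations lay above or below expectation depending on the genes counted. With median-ratio scaling the odds ratio was 1.36 for rises in both and 1.45 for falls in human with rises in rat, and 1.22 and 1.24 on the genes with a mean of at least 1 RPKM, so the odds ratio for rises in both was then not the higher. The Spearman rho of the log2 fold changes across genes, which are not independent replicates, was 0.024. Without scaling between libraries, the fold change differed between organisms for 6990 genes by the limma interaction term, so the general rat shift enters this count too. The exact tests above count genes as independent units, which they are not, and hold no spread between samples. Cells of a single lineage stand here beside a whole tissue of another organism, with genes matched by symbol only.

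In the authors' own deposited test, 1338 human transcripts had a false discovery rate under 0.05, 645 up, 690 down and 3 with no numeric fold, and for 1269 of them (94.8%) the gene was called here in the same direction, for 2 in the opposite. In rat it was 3804 transcripts, 2280 up and 1524 down, of which 2836 (74.6%) were called here in the same direction and 14 in the opposite. The authors' fold for ASCL2 was -4.46 in human and -50.5 for Ascl2 in rat.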

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

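Chosen only after the result was seen were the test of GC content in control replicate 4, the tests of mixing and of exchanged labels for wild type replicate 1, and the tests of scaling and of fetal blood cells for the rat lists. In 270 sets of 4 or 5 values, the extreme library's gap to its neighbour was compared with the group's range, and 21 sets (7.8%) held an extreme library where chance gives about 5%. Of these, 15 were in wild type replicate 1. Values below are that gap over the range.

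In wild type replicate 1 the ratio was 0.945 for the first principal component. It was 0.813 and 0.832 for Prl3d1_2 and Prl3d1_1, 0.721 for Rasd1, 0.733 for Hmox1, 0.766 for Fads6, 0.929 for Prl7a3 and 0.722 for Hk2, where this library was the highest wild type. It was 0.737 for Mmp15, 0.841 for Tfeb, 0.717 for Epcam, 0.743 for Plvap, 0.780 for Tek, 0.905 for Cdc20 and 0.718 for Phlda2, where it was the lowest. In the mutants it was 0.959 for Id1 in replicate 1 and 0.900 for depth in replicate 2. In human it was 0.882 for IGF2 in control replicate 4, 0.871 for MMP12 in knockdown replicate 2, and 0.911 and 0.850 for the shares of the 10 most abundant genes and of the mitochondrial genome in knockdown replicate 1.

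Wild type replicate 1 lay between the other wild types and the mutants. Exchanged labels are argued against by its Ascl2, at 23.8 times the highest mutant, and a bias by GC content by a Spearman rho of -0.08 across 9741 genes with the GC content of the same-named human gene, which stands in for that of the rat gene. A candidate explanation that stays open is mutant material mixed into this library: 283 genes at least 4-fold lower in the mutants stood a median 48.4% of the way to the mutants (quartiles 42.4 to 55.5) and 34 genes at least 4-fold higher stood at 53% (quartiles 41.7 to 64.3), a difference of 4.6 percentage points. Ascl2 stood at 43.0%. A disc of another stage or dissection was not tested, and grouping this library with the mutants against the other wild types gave 7836 changed genes, which points to this structure of the samples.

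Control replicate 4 lay apart from control replicates 1 and 3. Sequencing depth is argued against by a deviation as wide in genes above 100 RPKM (SD 0.68) as in genes of 1 to 5 RPKM (SD 0.58, ratio 1.17). GC content bias may explain part of it (rho -0.81 across 10602 genes). Control replicate 2, which shares the values between whole-read steps, had a rho of -0.52 against controls 1 and 3, so a different counting of read pairs could contribute. Against the rest of its own group, control replicate 2 had a rho of 0.08. That rest includes control replicate 4, with its strong trend of the same sign, so this value cannot weigh against such counting. Knockdown replicates 1 to 4, with at most 0.3% of such values, had -0.55, 0.72, -0.51 and 0.01. GC trends of this size thus also arose without such values. Fewer syncytiotrophoblast-like cells in that culture also stay open: after the GC trend was removed, the 33 syncytiotrophoblast genes had a median of -0.67 (quartiles -1.02 to -0.34; -0.71 before). CGA was at 6860 RPKM in control replicate 4 against 13400 in controls 1 and 3, CGB5 at 24.3 against 471, and PSG5 at 255 against 362.

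Labyrinth, erythroid and cell cycle genes fell together in the rat mutants. Scaling between libraries as the whole cause is argued against by a cell cycle median of -1.23 with median-ratio scaling (quartiles -1.49 to -0.68). For the labyrinth genes, a list meant to mark trophoblast, the median with median-ratio scaling was also -1.23 (quartiles -1.84 to -0.36). That scaling treats all genes of a library alike and does not measure blood cells. It therefore cannot decide whether fewer fetal blood cells contributed to the fall of this list. Among the labyrinth genes are Gcm1 (-2.43) and Dlx3 (-2.78), whose values here come from the main fit without that scaling. For the erythroid and cell cycle genes, fewer fetal blood cells could be part of it: 15 of 18 erythroid genes fell, but Hba-a2 (-0.36), Hbb (0.94) and Gata1 (0.05) did not pass the test. A smaller labyrinth and lower expression per cell also stay open and were not tested.

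The change in rat minus that in human differed from 0 by the limma interaction term for ASCL2 (-3.06), CCNE1 (-0.59), SLC25A30 (-2.22), DUSP4 (-3.72), RBPMS (-0.90), STK24 (0.31) and TBC1D2B (-2.32). These differences are without scaling between libraries and include the general rat shift.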

How the results depend on the processing

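Scaling between libraries, the filter of 1 RPKM in at least 4 samples, the test per transcript, leaving out control replicates 2 and 4, removal of GC trends, median-ratio scaling with erythroid genes left out, lists with 1 entry per gene (that with the highest mean), and the background and scaling of the shared calls were chosen after seeing the data. The log2 fold change of ASCL2 stayed negative and past the limma threshold in all 18 alternative settings run for each organism, from -2.13 to -1.88 in human (adjusted p 6.10e-06 to 0.00848) and from -6.13 to -4.78 in rat (4.22e-06 to 0.000950). With a pseudocount of 0.1, genes changed at least 2-fold numbered 2400 in human and 3150 in rat, since a smaller pseudocount enlarges folds of low genes. The human replicate numbers gave no sign of pairing the samples. With the replicate number as a block, 3295 human genes changed and shared calls fell from 989 to 629. The human proximal column list then missed the threshold (adjusted p = 0.0536, range over its camera settings 0.0441 to 0.316). Tested per transcript, 2439 human genes changed, with more tests to adjust for. The number of human lists called was 3 rather than 6 among genes with a mean of at least 1 RPKM, 3 with at least 1 RPKM in 4 samples and 0 with estimated correlations, which also gave 0 of 8 rat lists. In that limma camera test the human EVT list (unadjusted p = 0.0363) and the rat giant cell list (0.0432) had the lowest values, while fry called 8 human and 11 rat lists. By fry the human cell cycle (adjusted p = 0.112) and interferon (0.241) lists and the rat giant cell (0.105) and macrophage (0.16) lists lost their calls. It gained the human protease, fibroblast, imprinted domain and elsewhere-imprinted lists. In rat it gained the invasive, endothelial, mesenchymal, yolk sac and elsewhere-imprinted lists. Requiring 2-fold change in both organisms left 81 shared calls.

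Leaving out each library in turn gave 3516 to 5053 human and 7510 to 8825 rat genes changed, 1060 to 1320 and 1454 to 1822 changed at least 2-fold, 3 to 5 human and 8 to 9 rat lists, 706 to 1047 shared calls, and log2 fold changes of ASCL2 from -2.02 to -1.88 in human and -5.18 to -4.84 in rat. The lowest number of human lists, 3, came without knockdown replicate 1. Of the values of human lists under alternatives, 261 kept direction and side of the threshold, 35 lost the call and 4 gained it. For human named genes these numbers were 995, 47 and 12, for rat lists 309, 20 and 9, and for rat named genes 1149, 10 and 11. Of the lists and named genes, none that passed its test reversed under the alternatives run. The balance of human calls did, from 2866 up and 2293 down to 2243 and 2454 with upper-quartile scaling. Without control replicates 2 and 4 it was 1857 and 1871. The overlap between organisms reversed too: genes down in both had an odds ratio of 2.25 at 2-fold change in both but 0.82 among genes with a mean of at least 1 RPKM in both, and genes up in human and down in rat had 1.57 and 0.78. Causes were not tested except where stated. Settings written down in advance that need counts (other size factors, upper-quartile factors on counts, other count tests and filters on counts) were not run, since the tables give RPKM. In data simulated from the means and spread of the real genes, without using depth, 40% of 2-fold changes were recovered in human and 76% in rat. With only 50 genes changed at each fold, these shares may understate recovery in the real data.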

Other observations

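The gene lists of this part and the test of the rat libraries titled Het were chosen only after the results were seen, while the splits of the samples were planned. The camera p-values of these lists were adjusted only over the lists added here for each organism. Some of the lists hold genes that had already stood out, such as ANGPT2, Cyp11a1 and Hmox1, so these p-values are no independent support. In the human cells with ASCL2 knocked down, 8 of 12 entries (11 genes, as TAP2 has 2) of histocompatibility class I and its peptide loading fell and 0 rose, with a median of -1.07 (camera adjusted p = 4.85e-06, adjusted p = 0.116 with an estimated correlation). With TAP2 entered once, 7 of 11 fell (camera adjusted p = 2.04e-05). The peptide transporter TAP1 fell (-1.66), as did the light chain B2M (-1.25), HLA-G (-1.60) and HLA-C (-1.05), and HLA-A (0.03) did not pass the test. Of 12 steroid synthesis genes, 6 rose and 0 fell, with a median of 0.58 (camera adjusted p = 5.88e-05, adjusted p = 0.116 with an estimated correlation), among them CYP11A1 (1.6), FDX1 (1.47) and CYP19A1 (2.27). Of 8 angiogenic genes, ANGPT2 (3.95) and the receptors FLT1 (2.19) and ENG (2.40) rose and ANGPT1 fell (-0.56), which missed the list threshold (camera adjusted p = 0.0505), though not with median-ratio scaling (0.0445) or without control replicate 1, 2 or 3 or knockdown replicate 1 (0.0267 to 0.0462). The count of falls was 0 without control replicate 2, knockdown replicate 3 or control replicates 2 and 4, and with the replicate block. It was 2 without control replicate 4 or with upper-quartile scaling. Of 11 heat shock genes, DNAJB1 (0.92) and HSPA1B (1.02) rose (camera adjusted p = 0.136). With GC trends removed within groups 6 rose and 1 fell (camera adjusted p = 0.0819), with a mean of at least 1 RPKM 4 rose, and 1 rose without control replicate 1, 2 or 4 or knockdown replicate 2, 3 or 4.

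In the rat mutants, 9 of 12 steroid synthesis genes rose and 1 fell, with a median of 1.64 (camera adjusted p = 2.70e-08, adjusted p = 0.114 with an estimated correlation), and with median-ratio scaling 9 rose, 0 fell and the median was 1.93 (camera adjusted p = 1.56e-05). The cholesterol carrier Star (1.56), the lipoprotein receptor Scarb1 (1.76), Hsd3b2 (1.82) and Cyp11a1 (2.03) rose, and the receptor Ldlr fell (-0.52). Of 12 heat shock entries (10 genes, as Hspa1a and Hspa8 have 2 each), 6 rose, including Hmox1 (2.10), Hspb1 (1.26) and Hspa1b (2.51), and 2 fell, with a median of 0.29 (camera adjusted p = 0.000517, adjusted p = 0.207 with an estimated correlation), while with median-ratio scaling 7 rose, 0 fell and the median was 0.58 (camera adjusted p = 0.000997). With 1 entry per gene, 6 rose and 1 fell (camera adjusted p = 5.44e-05). With replicate pairs as a block, 6 entries rose and 0 fell. Only 1 fell without wild type replicate 3, 4 or 5 or mutant replicate 4, and 3 fell without mutant replicate 1. Of 9 angiogenic genes, the placental growth factor Pgf rose (1.71) and 4 fell (camera adjusted p = 0.323). Wild type replicate 1 had the highest wild type values of Hmox1 and Cyp11a1, 374 and 261 RPKM against group means of 183 and 151 RPKM. Among 8003 rat genes with a mean of at least 5 RPKM, mutant replicate 1 had 100 at least 2-fold below all other libraries and 1 as far above, against totals of 0 to 13 in the others.

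The rat libraries titled Het held 1.41% of the wild type mean of Ascl2. As a hypothesis, this level may fit discs whose expressed allele, or both alleles, carried the mutation, rather than discs that kept a working expressed allele. The genotypes were not tested.

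Among the 35 splits of the 8 human libraries, only the real split, 1, gave as many as 5159 changed genes. Again only 1 gave as many as 1223 changed at least 2-fold, and the highest of the others gave 1 and 0. Chance is thus unlikely for both counts, though 1 of 35 is the lowest share these splits allow. Every other split mixes the groups, so a real difference widens its spread and lowers its count. For the 6 human lists, 3 splits gave as many, the highest other also 6, so chance could not be excluded for that number. Among 100 splits of the 9 rat libraries, only the real split, 1, gave as many as 8356 changed genes or, again 1, as many as 1547 changed at least 2-fold. The highest other split, which set wild type replicate 1 with the mutants, gave 7836 and 1432, and the next gave 1. Chance is thus unlikely here too, at 1 of 100 splits, with the same limit. For the 8 rat lists, 17 splits gave as many, the highest other 13, so chance could not be excluded. Of the splits that part all 4 rat pairs, the 10 drawn besides the real one gave at most 1 changed gene.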
